A study of Mus musculus with 9 samples.

How the data were processed

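RNA came from microglia sorted by flow cytometry from mouse brain, pooled from 3 mice per library, and libraries were made with a kit for very low RNA input, per the labels' protocols. The sort gate is not given in the sources used here. Per the submitters' processing notes, the tools were CASAVA, cutadapt 1.13, STAR 2.5.3 and DESeq2 1.16.1, with the mm10 genome build; the role of each tool, the read counter and the gene annotation are not given in the sources used here.

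The deposited per-library table is named for normalized counts, but its values are on a log2 scale, from -2.14 to 20.05, with 3143 genes negative in all 9 libraries. The authors' transformation of these log2 values is not given in the sources used here; in the deposited tables the median of the table's gene means minus log2 of the authors' mean lies between -0.071 and 0.018, which places the values on the log2 scale of normalized counts. Folds from these values differ from those in the authors' comparison tables for abundant genes too, and beyond that comparison what the transformation does to folds was not tested. The authors' deposited comparison tables give, per the file headers, a mean signal per gene over libraries (base mean), a log2 fold change, a test score, a p-value and an adjusted p-value for each pair of ages. Whole reads could not be recovered from the values, so read totals are unknown and no test on read counts was run.

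The design fixed before the data were examined took the values for normalized counts and planned log2(value + 1). Because they are already on a log2 scale they were used as deposited. A gene was tested when its value was at least log2 of 10, 3.32, in at least 3 libraries, which kept 14955 of 22036 genes. A linear model with the 3 ages as groups was fitted to the 9 libraries with limma 3.58.1 in R 4.3.3, with a variance trend. Pairwise differences, the F test over 3 ages and the difference between the steps were tested with its two-sided moderated tests and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. Prior degrees of freedom were 4.57 beside 6 residual ones. An exact permutation test of 3 against 3 libraries cannot go below 0.1, so single genes rest on the model's pooled spread.

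Gene lists, 25 on biology and 12 of markers of other cell types, were fixed before the data were examined, and 954 of their 1028 genes were tested; the other 74 were not analysed here, 32 of them because they were below the filter on low values. Lists were tested with camera in limma with a preset correlation of 0.01, with Benjamini-Hochberg adjustment within each family, and again with an estimated correlation and with fry. Camera compares a list with the other genes, and fry tests whether a list's genes move one way on balance. Named genes were chosen by a rule: per comparison and direction up to 8 genes with the largest change among those called, with a mean of at least 50 in the higher group and no overlap between groups. Where fewer than 4 qualified, the next by unadjusted p were added up to 4 and given as values, and up to 3 members with the smallest p were added per called list and for 8 lists of prior interest. Unnamed gene models and pseudogenes were left out. A gene that the rule selects is not reported here. Neutrophil, monocyte and other markers given by name in the closing section were chosen for their level after the values were seen. Coordinates come from GENCODE M21 on GRCm38, the same build, which holds 99.8% of the tested symbols.

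The test was tested on simulated data with 200 changed genes among 14955. For old against young it recovered 60% of the genes changed by 0.5 on the log2 scale and 92% of those changed by 1; for middle-aged against young the shares were 50% and 92%. These shares may overstate the recovery in the real data. The changed genes were 50 each at 0.5, 1, 2 and 3, and many large changes ease the adjusted threshold. Simulated noise was independent between genes, with the same spread in all libraries. The 17 genes called in the real middle-aged against young comparison had a median log2 change of 0.961. Overlaps between the comparisons that share the young libraries were set against 100 simulations in which all 9 libraries were drawn around a common mean per gene. Alternatives planned before the data were examined covered pseudocounts, filters, scaling, variance settings, library weights, a replicate block, fits of 2 ages alone and leaving out each library. The immediate early score and the neutrophil score as covariates, removal of transcript length and GC trends and a pseudocount of 1 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.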

Results

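Gene expression was measured by RNA sequencing in microglia, the resident macrophages of the brain, sorted by flow cytometry from wild-type female mice of the C57BL/6 strain at 3 ages. The young mice were 6 months old, the middle-aged mice 15 months and the old mice 23 months. Each age had 3 libraries, and each library held RNA pooled from 3 separate mice, so the spread between libraries is a spread between pools of animals. The deposited table gives log2-scale values for 22036 genes, of which 14955 passed the filter on low values and were tested. Read totals per library are not given in the sources used here, so the depth is unknown. The first principal component held 34.7% of the variance and separated old replicate 3, at 29.9, from the other 8 libraries, which lay between -14.4 and 5.9. The ages did not overlap along it: young libraries lay from -14.4 to -9.14, middle-aged ones from -4.3 to 1.64 and old replicates 1 and 2 at 5.9 and 3.54. Old replicate 3 also had the largest residual SD, 0.202 on the log2 scale, against 0.0717 to 0.149 in the others.

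**Figure D1:**
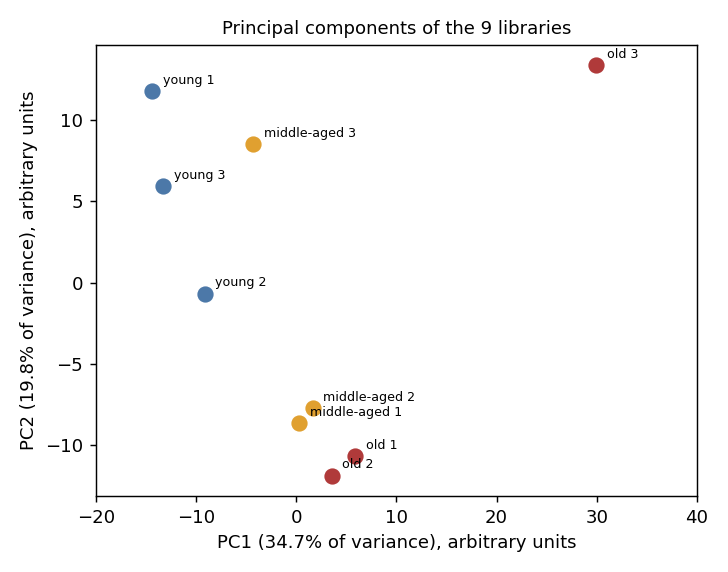
Principal components of the 9 libraries, computed from the deposited log2 values, with PC1 (34.7% of variance) on the horizontal axis and PC2 (19.8%) on the vertical axis in arbitrary units; each point is a library, coloured by age. Old replicate 3 lies at 29.9 on PC1, apart from the other libraries, and the ages do not overlap along PC1.

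The first comparison asks what differs in microglia by 15 months. Genes of the disease-associated microglia list, a set known from activated microglia, had the largest mean change of the 25 lists in middle-aged against young libraries, although camera did not call that list with an estimated correlation (Benjamini-Hochberg adjusted p = 0.113). Spp1, Lpl, Cst7, Gpnmb and Ch25h are on that list, and Cxcl13, Mmp12 and Pdcd1 are not. Spp1, which encodes the secreted matrix protein osteopontin, rose 5.12-fold (log2 2.36 ± 0.16 SE, n = 3 per group). Lpl, encoding lipoprotein lipase, rose 3.07-fold (log2 1.62 ± 0.13), Cst7, encoding the cysteine protease inhibitor cystatin F, rose 2.72-fold (1.44 ± 0.11), and the B-cell chemokine gene Cxcl13 rose 2.90-fold (1.53 ± 0.14). Gpnmb, a transmembrane glycoprotein gene, rose 3.52-fold (1.82 ± 0.25), and Ch25h, encoding cholesterol 25-hydroxylase, rose 2.12-fold (1.08 ± 0.13). The protease gene Mmp12 rose 2.01-fold and the checkpoint receptor gene Pdcd1 rose 1.95-fold. Adjusted p ranged from 0.000329 for Spp1 to 0.0389 for Mmp12 among these 8 genes (limma moderated test, Benjamini-Hochberg). Spp1 lies on chromosome 5 at 104435118 to 104441050, Lpl on chromosome 8 at 68880491 to 68907448 and Cst7 on chromosome 2 at 150570415 to 150578944 of the GRCm38 mouse genome.

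In all, 17 of the 14955 genes rose and 0 fell in middle-aged against young libraries at adjusted p under 0.05 (limma moderated test, Benjamini-Hochberg), and 1698 genes had an unadjusted p under 0.05. The groups did not overlap in 21.6% of genes, where chance gives 10%. No gene passed in the lower direction. The values nearest to it were those of Stab1, a scavenger receptor gene that is also among the border macrophage markers (log2 -0.55 ± 0.09), Tmem44 (-0.68 ± 0.11), the monoacylglycerol lipase gene Mgll (-0.54 ± 0.09) and the nucleoside transporter gene Slc29a1 (-0.44 ± 0.08). The count was 4 without young replicate 1, without young replicate 2 or without young replicate 3, and 49 without old replicate 3. Spp1, Lpl, Cst7 and Cxcl13 kept their calls whichever library was left out, and Ch25h, Gpnmb, Mmp12 and Pdcd1 kept theirs in 4, 3, 2 and 2 of 9 such fits. The authors' deposited table from DESeq2 called 410 genes lower and 528 higher for this pair of ages. Stab1, Tmem44, Mgll and Slc29a1 were among those called lower there (DESeq2 adjusted p = 3.96e-05, 1.06e-09, 3.27e-10 and 5.58e-07). The absence of falling genes therefore holds for the fit here only.

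Of 33 disease-associated genes tested at 15 months, 8 rose, 0 fell and 25 were not called, and 20 rose when adjusted over the list alone. Their mean log2 change was 0.55, and camera called the list higher (Benjamini-Hochberg adjusted p = 4.78e-22, and adjusted p = 0.113 with an estimated correlation). Of 25 inflammatory cytokine and chemokine genes, 1 rose (Cxcl13) and 24 were not called, and 15 rose adjusted over the list alone. That list was higher as a group, with a mean of 0.43 (camera, Benjamini-Hochberg adjusted p = 1.12e-15, and adjusted p = 0.0153 with an estimated correlation), and it was the 1 list of 25 still called with an estimated correlation. Tnf, a main inflammatory cytokine gene, had a log2 change of 0.80 ± 0.13, and Ccl12 had 0.60 ± 0.11, neither past the threshold over all genes here. In the authors' deposited table their DESeq2 adjusted p were 2.69e-05 and 4.93e-06. Of 33 immediate early response genes, which cells switch on within minutes of a stimulus, 0 were called and 24 rose adjusted over the list alone. Their mean was 0.40 (camera, Benjamini-Hochberg adjusted p = 7.66e-21, and adjusted p = 0.113 with an estimated correlation). Of 12 lists of markers of other cells, 4 were called by camera at 15 months and 0 with an estimated correlation. Neutrophil markers had a mean of 0.51 with 0 of 16 called, monocyte markers 0.41 with 0 of 16, erythrocyte markers 0.14 with 0 of 7 and border macrophage markers -0.20 with 0 of 16 (camera, Benjamini-Hochberg adjusted p = 0.000525, 3.17e-06, 0.0379 and 0.0011). Middle-aged replicate 2 adds to the first 2 means, with the highest score of the 9 libraries on both lists. As a mean deviation of the genes from their means over the 9 libraries, its neutrophil score was 0.918, against 0.0941 and 0.0163 in middle-aged replicates 1 and 3. Its monocyte score was 0.485, against 0.0581 and -0.136. In young replicates 1, 2 and 3 the neutrophil scores were -0.467, 0.132 and -0.171, and the monocyte scores were -0.423, -0.143 and -0.262. The monocyte scores of the 2 ages thus did not overlap, while the neutrophil scores did.

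Ribosomal protein genes were also higher as a group at 15 months, with 0 of 77 called, 30 rising adjusted over the list alone and a mean of 0.24 (camera, Benjamini-Hochberg adjusted p = 4.78e-22, and adjusted p = 0.22 with an estimated correlation). Among 27 homeostatic microglia genes 0 were called, 10 fell and 1 rose adjusted over the list alone, and the mean was -0.18 (camera, Benjamini-Hochberg adjusted p = 2.25e-07, and adjusted p = 0.113 with an estimated correlation). The 61 genes of the PI3K-AKT-mTOR pathway, which the series title names, were not called as a list (mean -0.04; camera, Benjamini-Hochberg adjusted p = 0.167) and 0 were called singly, with 1 falling adjusted over the list alone. Rptor, encoding the mTORC1 subunit raptor, had a log2 change of -0.48 ± 0.10. The 52 translation factor genes were not called as a list either (camera, Benjamini-Hochberg adjusted p = 0.0818), with 0 called singly and 1 rising and 1 falling adjusted over the list alone; Pabpc1, the poly(A)-binding protein gene, had a log2 change of 0.56 ± 0.10. In all, 13 of 25 lists were called, 12 higher and 1 lower, against 1 with an estimated correlation and 7 by fry, and another split of the 6 libraries called 19.

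**Figure D2:**
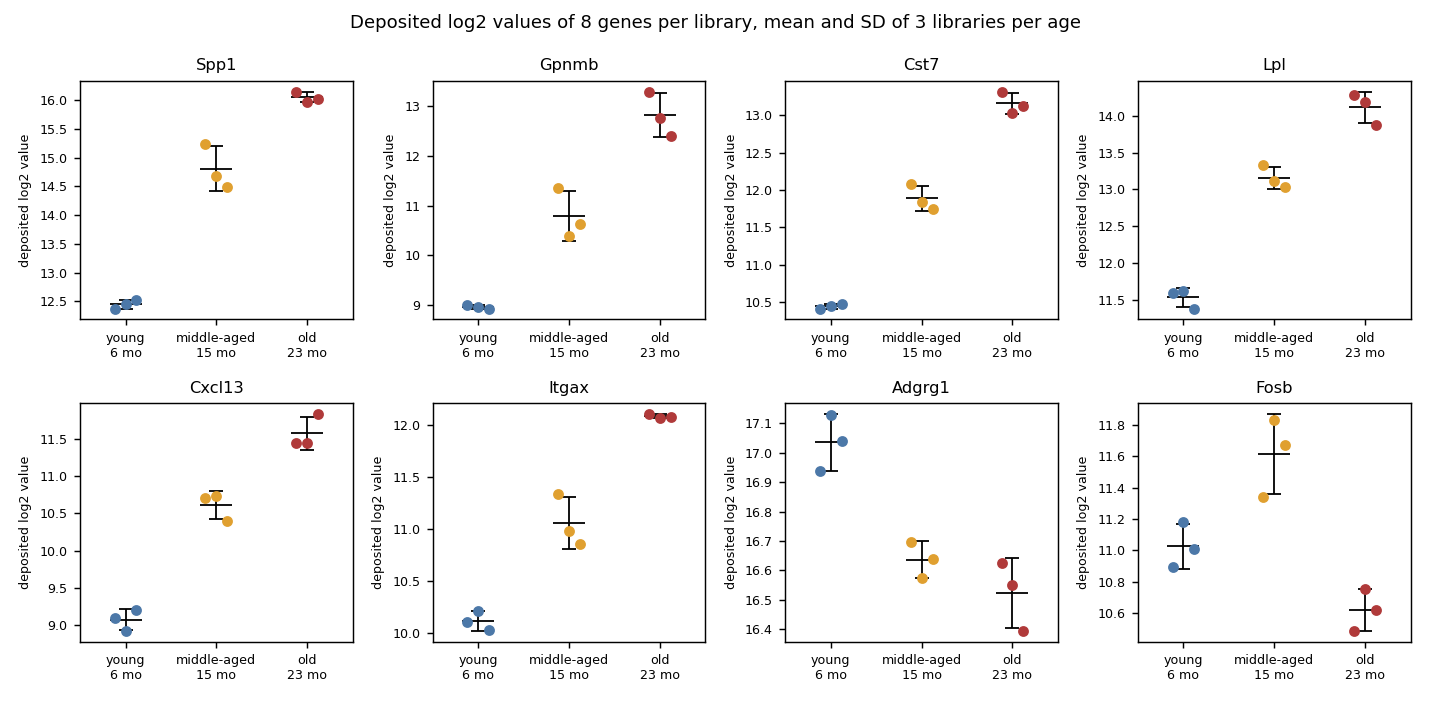
Deposited log2 values (vertical axes) of 8 genes in each library, grouped by age on the horizontal axes; points are libraries, horizontal marks are means and bars are SDs of 3 libraries. Spp1 has a mean of 12.45 in young, 14.80 in middle-aged and 16.05 in old libraries, and Fosb has its highest mean, 11.62, in the middle-aged ones.

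The second comparison spans 6 to 23 months, and 5 of the 8 rising genes named first, Gpnmb, Spp1, Cst7, Lpl and Itgax, are on the disease-associated list. Gpnmb rose 14.3-fold in old against young libraries (log2 3.84 ± 0.25 SE, n = 3 per group), Spp1 12.1-fold (3.60 ± 0.16), Cst7 6.56-fold (2.71 ± 0.11), Lpl 5.95-fold (2.57 ± 0.13) and Cxcl13 5.63-fold (2.49 ± 0.14). Rxrg, a retinoid X receptor gene, rose 4.10-fold (2.03 ± 0.19), Mmp12 4.03-fold (2.01 ± 0.15) and Itgax, encoding the integrin CD11c, 3.92-fold (1.97 ± 0.12). Adjusted p for these 8 genes ranged from 1.8e-06 for Cst7 to 0.000389 for Rxrg (limma moderated test, Benjamini-Hochberg), and all 8 were called whichever library was left out. In the lower direction, the orphan receptor gene Gpr165 fell to 0.546 of its young value (-0.87 ± 0.15), the myosin gene Myo1d to 0.572 (-0.81 ± 0.14), the lectin gene Cd209a to 0.618 (-0.70 ± 0.13) and the semaphorin gene Sema6d to 0.634 (-0.66 ± 0.12). Rgs7bp, Bank1 and Mgl2 fell by 0.75, 0.64 and 0.62 on the log2 scale. Of these falling genes Rgs7bp was called in each of the 9 fits that left out a library, Gpr165 and Myo1d in 6, Cd209a and Sema6d in 5, Bank1 in 4 and Mgl2 in 3. Mgl2 is also in the list of border macrophage markers, and Cd209a is in the list of dendritic cell markers. Igkv12-46, an immunoglobulin light chain segment, had a log2 change of -0.96 ± 0.13 here, but -0.131 with adjusted p = 0.057 in the authors' deposited table from DESeq2 with its own adjustment, so its fall depends on which of the deposited tables is read.

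Between young and old, 254 genes rose and 45 fell, 299 of 14955 in all at adjusted p under 0.05 (limma moderated test, Benjamini-Hochberg); 42 of them changed more than 2-fold. The groups did not overlap in 24.5% of genes, against 10% by chance. The count was 86 without young replicate 1, 122 without young replicate 2, 84 without young replicate 3 and 169 without old replicate 3.

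Of the 33 disease-associated genes, 23 rose, 0 fell and 10 were not called at 23 months, and 31 rose adjusted over the list alone. Their mean log2 change was 1.17 (camera, Benjamini-Hochberg adjusted p = 2.13e-46, and adjusted p = 0.0161 with an estimated correlation). Among 28 lipid handling genes 6 rose, 0 fell and 22 were not called, and 8 rose adjusted over the list alone (mean 0.37; camera, Benjamini-Hochberg adjusted p = 2.42e-06, and adjusted p = 0.0161 with an estimated correlation). They include Ch25h, up 3.77-fold (1.92 ± 0.13), and the fatty acid binding protein gene Fabp5, up 3.22-fold (1.69 ± 0.13), both also on the disease-associated list. Of 25 cytokine and chemokine genes 10 rose, 0 fell and 15 were not called, and 13 rose adjusted over the list alone (mean 0.50; camera, Benjamini-Hochberg adjusted p = 1.83e-11, and adjusted p = 0.0161 with an estimated correlation). The membrane-bound chemokine gene Cxcl16 rose 2.25-fold (1.17 ± 0.10) and the TNF family gene Tnfsf8 2.10-fold (1.07 ± 0.12). Monocyte markers were higher beside these groups, with a median log2 change of 0.37 and 3 of 16 called, while border macrophage markers had a median of -0.36 with 2 of 16 called lower (camera, Benjamini-Hochberg adjusted p = 5.86e-05 and 0.00636, and 0.386 and 0.426 with an estimated correlation).

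Genes of antigen presentation and of the interferon response were higher as groups at 23 months. Of 16 genes of MHC class I presentation 3 rose and 13 were not called, with 10 rising adjusted over the list alone (mean 0.41; camera, Benjamini-Hochberg adjusted p = 1.37e-09, and adjusted p = 0.0257 with an estimated correlation). The class I heavy chain gene H2-D1 rose 3.03-fold (1.60 ± 0.22) and H2-Q6 1.67-fold (0.74 ± 0.10); these genes have near-identical relatives, so how reads were divided among them is uncertain. The peptide transporter gene Tap1 rose 1.47-fold (0.56 ± 0.10). Of 43 type I interferon response genes 9 rose and 34 were not called, with 20 rising adjusted over the list alone (mean 0.35; camera, Benjamini-Hochberg adjusted p = 9.33e-15, and adjusted p = 0.0962 with an estimated correlation). Ifi27l2a rose 1.95-fold (0.97 ± 0.13) and the antiviral synthetase gene Oas1a 1.64-fold (0.72 ± 0.11). Of 9 MHC class II presentation genes 0 were called and 5 rose adjusted over the list alone (mean 0.21; camera, Benjamini-Hochberg adjusted p = 0.000214, and adjusted p = 0.0962 with an estimated correlation). T and NK cell markers had a mean of 0.15 in the same comparison, with 2 of 21 called higher, and oligodendrocyte markers had 0.19 with 1 of 12 called higher, Cspg4 (camera, Benjamini-Hochberg adjusted p = 7.43e-05 and 0.023, and 0.377 for both lists with an estimated correlation).

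Homeostatic microglia genes moved the other way. Of 27 tested, 6 fell, 0 rose and 21 were not called, and 14 fell adjusted over the list alone (mean -0.25; camera, Benjamini-Hochberg adjusted p = 1.16e-08, and adjusted p = 0.0797 with an estimated correlation). Adgrg1, an adhesion receptor gene, fell to 0.701 of its young value (-0.51 ± 0.08) and Ltc4s, encoding leukotriene C4 synthase, to 0.705 (-0.51 ± 0.09). P2ry12 and some other homeostatic genes were not analysed here.

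Genes of the protein synthesis machinery were higher in old libraries while the mTOR pathway list was not called. Of 77 ribosomal protein genes 13 rose, 0 fell and 64 were not called, and 51 rose adjusted over the list alone (mean 0.34; camera, Benjamini-Hochberg adjusted p = 1.7e-28, and adjusted p = 0.153 with an estimated correlation). Examples are Rps3a1 (0.56 ± 0.09) and Rps4x (0.50 ± 0.09); many ribosomal protein genes have processed pseudogenes that can share their reads. Of 52 translation factor genes 4 rose and 48 were not called, with 10 rising and 3 falling adjusted over the list alone (mean 0.08; camera, Benjamini-Hochberg adjusted p = 0.0107, and adjusted p = 0.31 with an estimated correlation). Among them Pabpc1 rose 1.52-fold (0.60 ± 0.10), the initiation factor gene Eif3h 1.35-fold (0.44 ± 0.09) and the elongation factor gene Eef1a1 1.41-fold (0.49 ± 0.11). Pabpc1 kept its call in 6, Eif3h in 2 and Eef1a1 in 1 of the 9 fits that left out a library. The translation factor list lost its camera call without old replicate 1. Of 61 PI3K-AKT-mTOR genes 2 rose, 1 fell and 58 were not called, with 3 rising and 2 falling adjusted over the list alone, and the list was not called (mean -0.03; camera, Benjamini-Hochberg adjusted p = 0.435). Prr5l, encoding an mTORC2-binding protein, rose 1.77-fold (0.82 ± 0.13) and Eif4ebp1, encoding the translation repressor 4E-BP1, rose 1.45-fold (0.54 ± 0.12), while the phosphatase gene Inpp5d fell to 0.773 (-0.37 ± 0.08). These are transcript levels, and phosphorylation and translation were not measured. Prr5l kept its call in 6, Eif4ebp1 in 2 and Inpp5d in 1 of the 9 fits that left out a library.

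**Figure D3:**
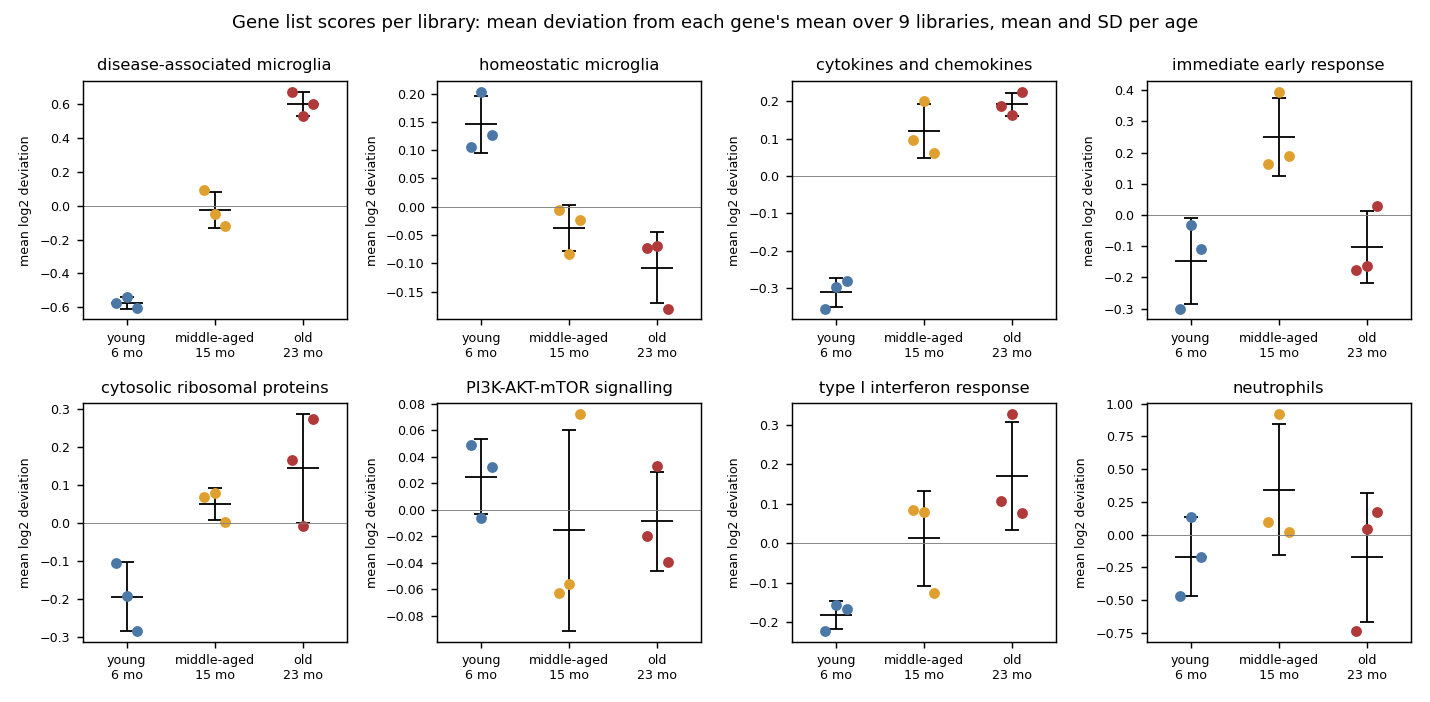
Scores of 8 gene lists in each library, as the mean deviation on the log2 scale of the list's genes from their means over the 9 libraries (vertical axes), by age (horizontal axes); points are libraries, horizontal marks are means and bars are SDs of 3 libraries. Disease-associated scores run from -0.605 to -0.538 in young and from 0.525 to 0.669 in old libraries, and neutrophil scores from -0.736 in old replicate 1 to 0.918 in middle-aged replicate 2.

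The third comparison covers 15 to 23 months. Gpnmb rose a further 4.05-fold in old against middle-aged libraries (log2 2.02 ± 0.25 SE, n = 3 per group), Cst7 2.41-fold (1.27 ± 0.11) and Spp1 2.37-fold (1.24 ± 0.16). The lipoprotein gene Apoe rose 2.26-fold (1.17 ± 0.19), the proteoglycan gene Cspg4, which is among the oligodendrocyte markers, 2.05-fold (1.03 ± 0.10) and the sulfotransferase gene Chst2 2.05-fold (1.03 ± 0.16). H2-D1 rose 2.88-fold and the ferritin heavy chain gene Fth1 2.52-fold, both from middle-aged values that differed widely between libraries (SDs of 0.51 and 0.54) and both with relatives or pseudogenes that can share their reads. The immediate early transcription factor genes Fosb and Egr1 fell to 0.501 (-0.997 ± 0.139) and 0.628 (-0.67 ± 0.11) of their middle-aged values. Adjusted p ran from 0.00407 for Cst7 to 0.0494 for Fth1 (limma moderated test, Benjamini-Hochberg). Dkk2, a Wnt antagonist gene, had a log2 change of 0.89 ± 0.11 here but 0.0565 in the authors' deposited table.

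In this comparison 24 genes rose and 2 fell, and 1522 had an unadjusted p under 0.05 (limma moderated test, Benjamini-Hochberg). The groups did not overlap in 12.9% of genes, against 10% by chance. The count was 3 without young replicate 1, without young replicate 2 or without young replicate 3, 4 without middle-aged replicate 2, and 0 when only the 6 libraries compared were fitted; Cst7 and Cspg4, 2 of the 19 called genes selected by name, kept their calls whichever library was left out, and the others did not.

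Between 15 and 23 months 12 of the 33 disease-associated genes rose, 0 fell and 21 were not called, and 27 rose adjusted over the list alone (mean 0.62; camera, Benjamini-Hochberg adjusted p = 1.3e-36, and adjusted p = 0.0324 with an estimated correlation). Of 28 lipid handling genes 4 rose and 24 were not called, with 6 rising adjusted over the list alone (mean 0.21; camera, Benjamini-Hochberg adjusted p = 4.03e-06, and adjusted p = 0.0324 with an estimated correlation). Lpl, Fabp5 and Ch25h rose by 0.96, 0.91 and 0.83 on the log2 scale. They and Apoe, the lipid handling genes called, are also on the disease-associated list, so these calls are not separate from that list's. Of 54 lysosome and phagocytosis genes 2 rose, Itgax (1.03 ± 0.12) and the receptor kinase gene Axl (0.93 ± 0.15), and 52 were not called, with 12 rising adjusted over the list alone (mean 0.15; camera, Benjamini-Hochberg adjusted p = 7.12e-09, and adjusted p = 0.191 with an estimated correlation). Itgax and Axl are also on the disease-associated list. Of 33 immediate early genes 2 fell and 31 were not called, with 17 falling adjusted over the list alone (mean -0.35; camera, Benjamini-Hochberg adjusted p = 8.08e-15, and adjusted p = 0.192 with an estimated correlation). Markers of other cells were called by camera in both directions, and 0 of the 12 lists were called with an estimated correlation. Neutrophil markers had a mean of -0.52 with 0 of 16 genes called (camera, Benjamini-Hochberg adjusted p = 0.000226). That mean rests largely on single libraries, as the neutrophil scores of replicates 1, 2 and 3 were 0.0941, 0.918 and 0.0163 in middle-aged mice. In old mice they were -0.736, 0.0435 and 0.17. T and NK cell markers had a mean of 0.19 with 0 of 21 called and 10 rising adjusted over the list alone (adjusted p = 8.11e-08 by camera with Benjamini-Hochberg adjustment, and 0.2 with an estimated correlation). Oligodendrocyte markers had a mean of 0.13 with 1 of 12 called, Cspg4, and astrocyte markers -0.10 with 0 of 15 (camera, Benjamini-Hochberg adjusted p = 0.0385 and 0.0403, and 0.352 and 0.788 with an estimated correlation). Ribosomal protein genes had a mean of 0.09 with 0 of 77 called (camera, Benjamini-Hochberg adjusted p = 2.67e-05, and adjusted p = 0.571 with an estimated correlation). Over the 9 fits that left out a library their mean ran from 0.0283 to 0.169, and the list lost its camera call without old replicate 3. The PI3K-AKT-mTOR list (adjusted p = 0.848), the cytokine list (0.172) and the translation factor list (0.205) were not called by camera with Benjamini-Hochberg adjustment.

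Across the 3 ages together 125 genes differed (limma moderated F test, Benjamini-Hochberg adjusted p under 0.05). For 0 genes did the step from 15 to 23 months differ from the step from 6 to 15 months, where 1181 had an unadjusted p under 0.05 (limma moderated test, Benjamini-Hochberg; smallest adjusted p = 0.405). All 17 genes that rose by 15 months were also called, higher, at 23 months. Simulated unchanged groups sharing the young libraries gave an overlap of 0 genes on average over 100 simulations, and independent lists of these sizes would share 0.289. In unchanged groups hardly any gene is expected to be called. The simulated overlap therefore cannot show how much overlap the shared young libraries give among genes that are called. Across genes, the fold changes at 15 and 23 months had a Pearson r of 0.649, where simulated unchanged groups gave 0.501, and a covariance of 0.0252 against a simulated 0.00914, a difference of 0.0161. Genes are not independent replicates, and part of the excess overlap may come from the shared young libraries, which are too few to divide.

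The authors' deposited tables, made pairwise with DESeq2, called more genes at adjusted p under 0.05: 938 in middle-aged against young, 1230 in old against young and 199 in old against middle-aged mice. In that order, 528, 762 and 129 of them were higher and 410, 468 and 70 lower. Of the genes called here, 17 of 17, 294 of 299 and 25 of 26 were called in the same direction there. In old against young the authors' deposited table gives log2 changes of 4.57 for Spp1, 4.10 for Gpnmb, 3.55 for Cst7, 3.01 for Rxrg and 2.82 for Ch25h, where the fit here gave 3.60, 3.84, 2.71, 2.03 and 1.92. In middle-aged against young it gives 2.31 for Spp1 and 1.58 for Gpnmb, against 2.36 and 1.82 here, and in old against middle-aged 1.02 and 1.18, against 1.24 and 2.02 here. The folds given for single genes therefore hold for the deposited log2 values.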

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

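The comparison with macrophage and monocyte markers, the neutrophil and immediate early covariates, their separate use on each list, the slopes within ages, and the length and GC correction were chosen only after the data were seen. For 10 gene lists the step from 15 to 23 months differed from the step from 6 to 15 months by camera with the preset correlation, and for 0 of them with an estimated correlation. The second step minus the first, as a mean on the log2 scale, was -0.75 for immediate early genes, -0.36 for cytokines and chemokines, -0.15 for ribosomal proteins and -0.10 for the respiratory chain. It was 0.15 for lysosome and phagocytosis genes, -0.25 for cell cycle genes and -0.20 for senescence and DNA damage genes. Among markers of other cells it was -0.41 for monocytes, -1.03 for neutrophils and 0.24 for T and NK cells.

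As lists, immediate early genes (0 of 33 called) and cytokines (1 of 25) were higher in middle-aged than in young libraries and immediate early genes (2 of 33) lower in old than in middle-aged ones by camera with the preset correlation, with Benjamini-Hochberg adjusted p of 0.113, 0.0153 and 0.192 when the correlation was estimated. Within ages, libraries with higher immediate early scores had higher cytokine scores (Pearson r = 0.857 over 9 libraries, exact one-sided permutation p = 0.037 over 216 arrangements; Spearman rho = 0.767, exact permutation p = 0.0417; r = 0.725 without middle-aged replicate 2 and old replicate 3; 2 relations were computed, this and that with neutrophil scores), as activation during dissociation and sorting would give, and with the immediate early score as a covariate the cytokine mean at 15 months was 0.295 in place of 0.431, 68.5% of it. With the neutrophil score as a covariate that mean was 0.389, 90.2% of it (84% to 97.8% without each library in turn), which argues against neutrophil RNA as the whole cause of the cytokine change. At 23 months neutrophil and immediate early scores differed from young ones by -0.006 ± 0.359 and 0.043 ± 0.104 (SE), so the cytokine change of 0.504 would need slopes on them of at least 0.578 and 1.7 even at the upper 95% limits of these differences, 0.872 and 0.297; the slopes within ages were 0.0825 and 0.342, with upper 95% limits of at most 0.225 and 0.726 whichever library was left out, which argues against neutrophil RNA and activation as the whole cause there, although the excess of the cytokine change over the neutrophil one, 0.51 ± 0.331 (SE), is uncertain beside that over the immediate early one, 0.46 ± 0.0713. Activation and age cannot be told apart for both lists at 15 months, nor neutrophil RNA and age for immediate early genes, whose mean was 0.275 in place of 0.397 with the neutrophil score, 69.3% of it (59.4% to 84.3%), and 0.324 in place of 0.412 with the cytokines included (78.7%), since the shares with all libraries lie between the bounds of 50% and 80%.

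Disease-associated genes were higher in old than in young libraries, with a median of 0.922 and 23 of 33 called. A single library does not account for it, since the median was 0.999 without old replicate 3. More monocytes or border macrophages as the whole source is argued against by the medians. The disease-associated one exceeded that of monocyte markers by 0.558 and that of border macrophage markers by 1.28. Shuffling the fold changes of genes between the lists gave permutation p = 0.00847 and 1e-05, the latter the smallest that 100000 permutations can give. These p-values treat genes as independent, although the disease-associated genes had an estimated correlation of 0.251. They do not measure the spread between libraries. Some monocyte RNA stays open, as monocyte markers were higher by a median of 0.365. A change of microglia with age is a hypothesis that may fit, and it was not tested apart from other differences between the age groups.

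Ribosomal protein genes were higher in old than in young libraries, with a median of 0.349 and 13 of 77 called, but the list was called by camera only with the preset correlation (Benjamini-Hochberg adjusted p = 1.7e-28, and 0.153 with an estimated correlation). After each library's trends on transcript length and GC content were removed the median was 0.309 (camera p = 0.0727 with an estimated correlation), which argues against those trends as the whole cause. Outside the ribosomal and respiratory chain lists, 5565 genes of up to 2510 bases had a median of 0.014. They are not matched in length to the ribosomal genes, whose median length was 1094 bases. The respiratory chain genes left out of that set had a median of 0.24, and 0.186 after the correction. Without old replicate 3 the ribosomal median was 0.288, which argues against that library as the whole cause. The genes moved together within ages, with an estimated correlation of 0.585, and old replicate 2 had a score of -0.009 against 0.166 and 0.272 in the other old libraries. A difference in RNA quality or handling between pools was not tested, and age stays open.

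With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real split called 17 genes and 13 lists in middle-aged against young libraries, where the highest other splits called 0 genes and 19 lists, and 3 of 10 splits called as many lists. It called 299 genes and 18 lists in old against young, with 0 and 14 as the highest of the others, and 26 genes and 15 lists in old against middle-aged, with 0 and 7. For each of these last 4 counts, and for the 17 genes, 1 of 10 splits, the real one, gave as many. Of 100 drawn labellings of the 9 libraries, 89, 96 and 98 were separate splits for the F test, the unequal steps and the overlap. For the 125 genes that differed across ages 1 of 89 splits, the real one, gave as many, the highest other being 7. For the 17 genes called at both ages it was 1 of 98, the highest other being 3. These are the smallest shares that 89 and 98 splits can give, so chance is made unlikely, not excluded. The labels of all 9 libraries were shuffled, so these shares test for any difference between ages. They do not test whether the changes at both ages are shared. The 17 genes are all those called in middle-aged against young libraries. For unequal steps the real count was 0, which all 96 splits reach by necessity, so this count says nothing about chance. The highest, 54, came from a split with the 3 young libraries as its middle group, a structure of the samples by age; with the real ages and young or old as the middle group the counts were 191 and 141.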

How the results depend on the processing

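The immediate early and neutrophil covariates, the length and GC correction and the pseudocount of 1 were chosen after seeing the data. Tests on whole reads with edgeR or DESeq2 were planned and not run, because reads could not be recovered, and the unknown depth limits what can be said of low genes. A change of direction was counted as a reversal only where the result was called in the main or the alternative fit. Over all alternatives 3689 results on named genes kept their side of the threshold without such a reversal, 506 lost and 77 gained a call and 0 reversed. For lists these numbers were 1256, 106, 12 and 2. The 2 that reversed, both at 15 months with the immediate early score as a covariate, were the oxidative stress list, with a mean of -0.0258, and the cell cycle list, with -0.0749. Unless fewer samples or genes are named, the cause was not tested.

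Counts of called genes, in the order middle-aged against young, old against young and old against middle-aged, were 17, 299 and 26. Library weights gave 312, 1609 and 62, with 1365 genes across the 3 ages and 216 called at both ages, in place of 125 and 17. Without a filter, which tests more genes, they were 10, 170 and 9, with 10 called at both ages, and with a filter at a value of 50 middle-aged against young gave 29, old against middle-aged 47 and both ages 28. No variance trend gave 3 for old against middle-aged. Fits of the 2 ages alone, with fewer samples, gave 153 for old against young and 0 for old against middle-aged. The immediate early covariate gave 0 for middle-aged against young, 0 for old against middle-aged and 0 at both ages, and the neutrophil covariate 8, 2 and 8. Called lists, 13 in middle-aged against young, 18 in old against young and 15 in old against middle-aged, were 1, 4 and 2 with an estimated correlation, and fry called 7 in the first and 5 in the last; the immediate early covariate left 5 in the first. Quantile normalization, equal totals, robust estimation, the other pseudocounts and the length and GC correction kept each of these counts within 1.5 times.

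The replicate numbers do not pair the libraries: correlations of deviations between libraries with the same number ran from -0.24 to 0.23, and 3 of 9 libraries correlated best with their own number. With a replicate block the counts were 11, 185 and 14, with 80 across the 3 ages and 11 at both ages.

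Leaving out each library, with fewer samples, gave 4 to 49 genes for middle-aged against young, 84 to 322 for old against young, 3 to 23 for old against middle-aged, 51 to 141 across the 3 ages, 4 to 39 at both ages and 0 to 5 with unequal steps. Lists ranged from 10 to 20, 16 to 19 and 10 to 15. For middle-aged against young the count was 4 without any 1 of the young libraries, 6 and 10 without middle-aged replicates 1 and 3, 7 and 10 without old replicates 1 and 2 and 49 without old replicate 3, whose spread was the largest. For old against young it was 86, 122 and 84 without young replicates 1, 2 and 3, 192 and 172 without middle-aged replicates 1 and 2, and 151 and 169 without old replicates 1 and 3. For old against middle-aged it was 3 without any 1 of the young libraries, 4 and 12 without middle-aged replicates 2 and 3, and 9, 9 and 14 without old replicates 1, 2 and 3. Across the 3 ages it was 53, 64 and 51 without young replicates 1, 2 and 3 and 68 without old replicate 1. Unequal steps gave 5 genes without middle-aged replicate 2 and 1 without middle-aged replicate 3. Of the named genes called, 4 of 9, 23 of 55 and 2 of 19 kept the call in all 9 fits.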

Other observations

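Several gene groups of metabolism and stress were higher in old than in young libraries. Of 26 glycolysis and HIF response genes 4 rose, 0 fell and 22 were not called, with 14 rising and 2 falling adjusted over the list alone (mean 0.22; camera, Benjamini-Hochberg adjusted p = 1.83e-05, and adjusted p = 0.159 with an estimated correlation). The oxygen sensor gene Egln3 rose 2.46-fold and the glycolytic enzyme genes Tpi1 and Aldoa rose 1.52-fold and 1.43-fold. Of 27 oxidative stress genes 3 rose, with 10 rising adjusted over the list alone (mean 0.26; camera, Benjamini-Hochberg adjusted p = 1.17e-06, and adjusted p = 0.0962 with an estimated correlation): the peroxiredoxin gene Prdx1 rose 1.75-fold, Fth1 2.46-fold and the glutathione peroxidase gene Gpx1 1.53-fold. Of 73 respiratory chain genes 2 rose, Atp5j and Cox6c, with 17 rising adjusted over the list alone (mean 0.23; camera, Benjamini-Hochberg adjusted p = 3.4e-14, and adjusted p = 0.16 with an estimated correlation). Atp5j kept its call in 2 and Cox6c in 1 of the 9 fits that left out a library. Of 30 genes of the unfolded protein and integrated stress response 3 rose, among them the asparagine synthetase gene Asns, 1.75-fold, with 4 rising adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00652, and adjusted p = 0.285 with an estimated correlation). That list lost its camera call without young replicate 1, and its mean ran from 0.0746 to 0.147 over the fits that left out a library.

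The complement genes C1qa and C1qc rose 1.61-fold and 1.46-fold from young to old, 2 of 18 in their list, with 4 rising adjusted over the list alone (mean 0.16; camera, Benjamini-Hochberg adjusted p = 0.00913, and adjusted p = 0.16 with an estimated correlation). Of 25 cholesterol synthesis genes 1 rose, Insig1, by 0.59 ± 0.12 (SE) on the log2 scale, with 6 rising adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.63e-05, and adjusted p = 0.0797 with an estimated correlation). The cell cycle regulator genes Ccng1 and Cdkn1a rose 1.47-fold and 1.53-fold, 2 of 20 in the senescence and DNA damage list, with 4 rising adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000239, and adjusted p = 0.095 with an estimated correlation). Over the 9 fits that left out a library, C1qa kept its call in 8, Ccng1 and Cdkn1a in 3 each, and C1qc and Insig1 in 2 each. The purine receptor gene P2rx4 rose 1.45-fold from 15 to 23 months and was not called in any fit that left out a library. Lists of NF-kB signalling (adjusted p = 0.0833), the inflammasome (0.717), autophagy (0.435) and TGF-beta signalling (0.179) were not called in old against young libraries by camera with Benjamini-Hochberg adjustment.

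Some transcripts of neutrophils were abundant in all the age groups. The neutrophil list had a median level of 13.2 on the deposited log2 scale, beside 16.2 for the homeostatic microglia genes. The granule protein genes Ngp and Ltf had means of 17.36 and 16.40 in young libraries, and S100a8 had 14.97; these 3 were chosen for their level after the values were seen. Ngp had means of 18.10 in middle-aged and 17.28 in old libraries, with SDs of 0.68 and 0.62 (n = 3). The sort gate is not given in the sources used here. Border macrophage and monocyte markers had median levels of 11.7 and 11.4. Markers of astrocytes, neurons, oligodendrocytes and the choroid plexus lay far lower, with median levels of 7.41, 5.59, 6.15 and 6.39.

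H2-D1 and Fth1 varied alike between the middle-aged libraries. H2-D1 was 14.30, 14.44 and 15.25 in middle-aged replicates 1, 2 and 3, and Fth1 was 16.28, 16.48 and 17.30, while in old libraries they lay between 16.06 and 16.42 and between 17.88 and 18.13.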
